A study of Myodes rufocanus with 2 samples.

How the data were processed

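Messenger RNA sequencing libraries had been made from 1 µg of total RNA of whole eyeballs of *Myodes rufocanus* with a Hieff NGS MaxUp kit for mRNA and Illumina sequencing, per the labels' protocols. The labels name 1 normal eyeball and 1 lens clouded eyeball and the design text compares LE with RE, but nothing in the labels or tables ties LE or RE to either eyeball. The direction of every ratio is therefore RE over LE. The submitters' processing notes name FastQC 0.11.2, Trimmomatic, Bowtie2, Salmon and DESeq2 without giving their roles. The deposited values are estimated counts, unscaled and partly fractional, for the 214801 genes of a de novo assembly that carries Trinity identifiers, each with annotation columns of best database matches. No genome build or coordinates come with them, so positions are not given here. LE held 24483903 counts over 183195 assembled genes above 0, and RE held 19967599 counts over 168720. In both tables, 89 lines were the overflow of long annotation cells and were joined to the line before.

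Each assembled gene, called a feature here, was given a gene symbol from the table's own annotation. The symbol in parentheses in the best nucleotide match was used for 38337 features. The name of the best protein match was used for 4390, through pairs of name and symbol that other features of the same tables carry. A short list of protein names, written by hand after the tables had been read, served for 182. Vole mitochondrial features were named by their mitochondrial gene where 1 was given, and 32 features were of this kind. Where both matches gave a symbol, they gave the same one for 99.0% of 21838 features. The remaining 171860 features had no symbol and held 13.5% of the counts in LE and 10.8% in RE. Features whose best nucleotide match was the human or the house mouse mitochondrial genome were given no symbol. Counts were summed by symbol, over 15089 symbols, and rounded to whole numbers after summing.

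Log2 ratios were computed from these sums, scaled by factors from the trimmed mean of M-values in edgeR 4.0.16 under R 4.3.3, and the factors were 1.19 for LE and 0.838 for RE. A ratio was computed from the counts with no pseudocount, and a library at 0 was set to 3 counts. No ratio is given where both libraries had at most 3 counts. Each ratio has an exact 95% interval from the binomial distribution of the counts conditional on their sum (Clopper-Pearson). Shares of a library have exact binomial 95% intervals. Symbols with a summed count of at least 100 were compared, and a difference of at least 2-fold was counted in each direction. There is 1 library per eyeball, so no gene or list was tested for a difference.

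Before the data were examined, 40 lists of genes were written down for the cell types of the eye and its surroundings and for pathways that bear on the lens. These are crystallins, fibre cell genes, lens transcription factors, lens capsule, rods, cones, bipolar cells, amacrine and horizontal cells, ganglion cells, Müller glia, pigment epithelium, melanin, corneal epithelium, stroma, iris and ciliary body, eye muscle, glands, erythroid cells, macrophages, other leukocytes, vessels, complement, inflammatory cytokines, interferon response, antigen presentation, antioxidant enzymes, heat shock proteins, unfolded protein response, fibrosis, polyol pathway, lens ion transport, apoptosis, proliferation, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, immediate early genes, circadian clock and hypoxia. The median log2 ratio of each list with at least 3 members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean abundance. The percentile describes these 2 libraries, and a list is said to stand apart when it is at or below 2.5 or at or above 97.5. The genes named in the text were also chosen by a rule fixed beforehand. It takes the 12 highest and 12 lowest ratios among symbols with at least 1000 counts, ordered by the bound of the counting interval nearest 0. Proteins of transposons or retroviruses and symbols whose best match was not to a mammal are left out of this ranking. It adds the most abundant member and the 3 members with the largest ratios of each list, the 5 most abundant symbols of each library, and the crystallins. Not every gene that the rule takes is named, and the values of some are not reported here.

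The steps were tested on simulated data with Poisson counts at the abundances and depths of these libraries, with the mitochondrial genes raised 4-fold and 200 genes changed by known folds, over 11808 genes for the comparison of RE with LE. All 50 genes changed 4-fold and all 50 changed 3-fold were found at least 2-fold apart on the right side. For the 50 genes changed exactly 2-fold the median size of the recovered log2 ratio was 0.97, with 19 of them found at least 2-fold apart, and 48 of 50 genes changed 1.5-fold had an interval on the right side of 0. Among 11579 unchanged genes, 95.3% of the intervals held 0. The simulated counts varied by Poisson error only, and the changes of the 200 genes were split evenly between up and down. The simulation therefore checks the steps, and neither the choice of scaling nor the intervals in the real libraries.

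The alternatives planned before the data were examined were size factors from DESeq2 1.42.0, total counts, total counts without crystallin, haemoglobin and mitochondrial genes, the most abundant feature of each symbol in place of the sum, each feature on its own, minimum summed counts of 1, 20 or 1000, and an interval wholly beyond 2-fold. Those added after the data had been seen leave out features whose best match is a primate sequence, take the symbol from the protein match first, or keep only features with a protein match. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.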

Results

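RNA sequencing was carried out on whole eyeballs of the grey red-backed vole *Myodes rufocanus*, a wild rodent. The labels describe 1 normal eyeball and 1 lens clouded eyeball, in which the normally transparent lens had turned opaque. The estimated counts come as 2 libraries, LE and RE, and no label states which of them is the normal eyeball. Ratios are therefore given as RE over LE, and neither library is called normal or clouded. LE held 24483903 counts and RE held 19967599. With 1 library per eyeball the difference has no replicate check, so no p-value is given for a gene or a list, and the values compare these 2 libraries and not the 2 states of the lens. The intervals of single ratios and of shares are exact 95% intervals for counting error only, and they treat reads as independent. PCR reads without molecular identifiers are not independent molecules, so these intervals can be too narrow. Intervals of list medians reflect the spread among genes instead.

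The comparison of RE with LE, the one the design text names, asked which genes were expressed at different levels in the eyeballs. Transcripts of the mitochondrial genome were higher in RE, with a median log2 ratio of 2.36 over 8 genes. Lens crystallins, the structural proteins that fill the lens fibre cells, were lower in RE, with a median of −0.46 over 11 genes, whereas the transcription factors that direct lens development were higher, with a median of 0.46 over 11 genes. Genes for ribosomal proteins, glycolysis and the nuclear-encoded part of oxidative phosphorylation were lower in RE, with medians of −0.47, −0.50 and −0.50. Inflammatory cytokine and chemokine genes were higher, with a median of 0.88. Among 12114 gene symbols with at least 100 counts in both libraries together, 333 were at least 2-fold higher in RE and 121 were at least 2-fold lower.

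The size of these differences was modest for most genes. The central 50% of symbols had log2 ratios between −0.32 and 0.31, and the symbols at least 2-fold apart were 3.75% of those measured. The 95% counting interval lay wholly above 0 for 4089 symbols and wholly below 0 for 4170, so an interval without 0 is common here. The interval lay wholly beyond 2-fold for 170 symbols higher in RE and for 29 lower. The split between higher and lower depended on the scaling. With the trimmed mean of M-values, 73.3% of the symbols at least 2-fold apart were higher in RE. Scaled to the total counts, 64 were higher and 1674 lower, so that 3.68% were higher, and scaled to the totals without crystallin, haemoglobin and mitochondrial genes, 267 were higher and 167 lower, so that 61.5% were higher. The median log2 ratio of all symbols was −0.01 under the main scaling and −0.52 with total counts, under which every ratio was 0.51 lower. Directions are given relative to the bulk of the genes, and any positive ratio smaller than 0.51 would lie below 0 with total counts. The percentile of a gene list sets its median against those of random lists of other genes, scaled in the same way.

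**Figure D1:**
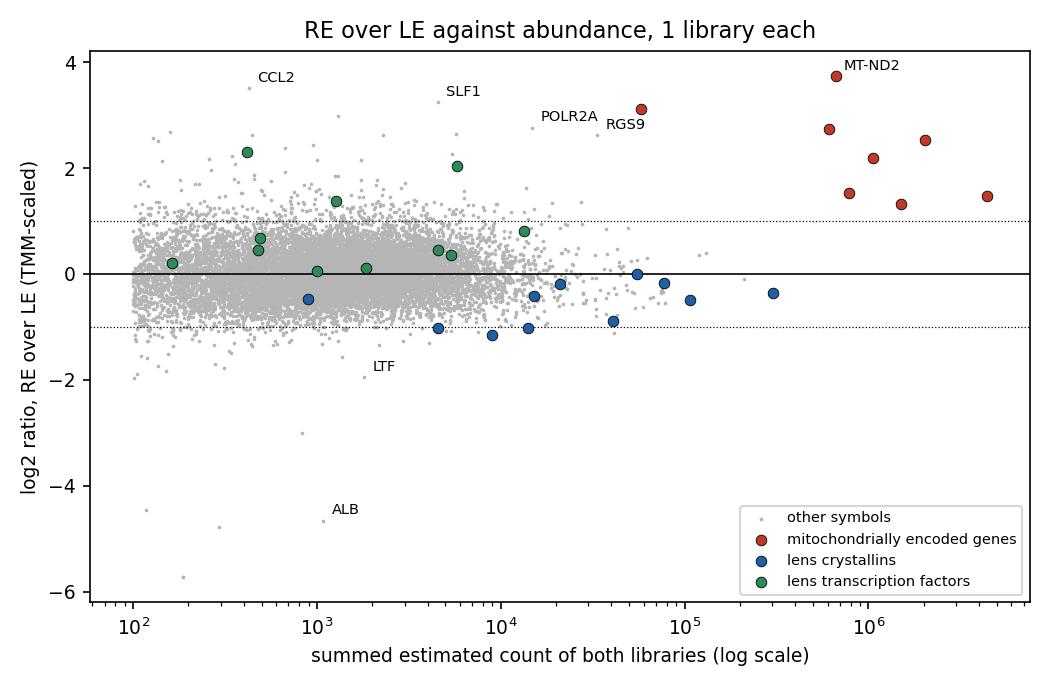
Each point is 1 gene symbol with at least 100 counts, with the summed estimated count of both libraries on a log scale on the x axis and the log2 ratio of RE over LE, after scaling by the trimmed mean of M-values, on the y axis. Dotted lines mark 2-fold. Coloured points are mitochondrially encoded genes, between 1.32 and 3.74, lens crystallins, all below 0, and lens transcription factors, all above 0. With total counts every point would lie 0.51 lower, which would place 6 of the 11 transcription factors below 0.

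Transcripts assigned to the mitochondrial genome made up 14.69% of the counts in LE (exact binomial 95% interval 14.68% to 14.71%) and 37.85% in RE (37.82% to 37.87%). All 8 measured genes were more than 2-fold higher in RE. MT-ND2, a subunit of respiratory complex I, had the highest log2 ratio of the ranked symbols with at least 1000 counts, at 3.74 (95% interval 3.73 to 3.75). MT-ND6 followed at 3.11 and MT-ATP6, a subunit of the ATP synthase, at 2.74. The most abundant, MT-CO1, a subunit of cytochrome c oxidase, was lower in the order at 1.48, and MT-CO3 was the lowest of the 8 at 1.32. Assembled mitochondrial features can span neighbouring genes, so the division of reads among these 8 genes is uncertain, and the other 5 genes of the list had no feature of their own with enough counts. Of the nuclear symbols in this ranking, SLF1, a DNA repair factor, had the highest ratio at 3.25 (706 and 3855 counts in LE and RE). Others among the 12 highest ratios were those of POLR2A, the largest subunit of RNA polymerase II, at 2.76 (3026 and 11794 counts), PHLDA1 at 2.62 and LYL1, a transcription factor of blood cell development, at 2.26. The PHLDA1 ratio came mostly from its most abundant feature, at 2.79, while the other 2 together were at 0.57 (0.05 to 1.08). RGS9, which speeds the recovery of photoreceptors after light, had a ratio of 2.62, but this rested on 1 assembled feature without a protein match. The other 5 RGS9 features together had a ratio of 0.07 (−0.04 to 0.17).

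Among the abundant symbols ranked, the lowest ratio was that of ALB, serum albumin, at −4.66 (1056 counts in LE and 24 in RE). Its best match in the table was a house mouse sequence, and a house mouse source of these counts was not tested. LTF, the tear protein lactoferrin, had a ratio of −1.94 (−2.15 to −1.74). IGFBP2, a binding protein of insulin-like growth factors, had a ratio of −1.57, and SLC2A4, the insulin-responsive glucose transporter, −1.34. S100A4, a calcium-binding protein of motile cells, stood at −1.27 and PRPH2, which shapes the rims of photoreceptor discs, at −1.11. Of the 121 symbols at least 2-fold lower in RE, 6 drew most of their counts from features whose best match was a primate sequence, against 0 of the 333 higher.

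The lists of crystallins and of lens transcription factors lay in opposite directions, in RNA of whole eyeballs and not of lens alone. All 11 crystallins with enough counts had ratios below 0. The interval lay below 0 for 10 of them, against 4170 of all 12114 symbols. That share is not matched on abundance, and more counts give a narrower interval. The list's median of −0.46 was at percentile 0.12 of random lists of the same size and abundance. The differences were largest for CRYBA4 at −1.15 (−1.23 to −1.08), CRYBB1 at −1.02, CRYGB at −1.01 and CRYGS at −0.89, although the less abundant of the CRYGS features was at 0.74 (0.59 to 0.90). The most abundant crystallin, the chaperone CRYAA, had a ratio of −0.36 (210028 and 93719 counts), CRYBB2 −0.48, CRYGN −0.46, CRYBB3 −0.42, CRYBA2 −0.19 and CRYBA1 −0.17. CRYAB, the other alpha-crystallin chaperone, was at −0.01 (−0.03 to 0.02), a difference not detectable at this depth. CRYGA and CRYGD had at most 3 counts in each library, so no ratio is given, and gamma-crystallins are near-identical paralogs whose reads the assembly may not keep apart. Crystallins together made up 1.84% of the counts in LE (1.83% to 1.84%) and 0.992% in RE (0.987% to 0.996%). Of 17 genes of lens fibre membranes, cytoskeleton and organelle loss, 13 had ratios below 0 and 4 above, with a median of −0.24 at percentile 4.26. The fibre membrane protein LIM2 was at −1.02, the beaded filament protein BFSP1 at −0.96 and LGSN at −0.86.

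All 11 lens transcription factors had ratios above 0, with the interval above 0 for 8, and their median of 0.46 was at percentile 99.6. With total counts the median was −0.051, so the direction holds only relative to other genes. TFAP2A had a ratio of 2.31 (1.99 to 2.64), SIX3 2.04 (1.96 to 2.13), MAF 1.38 and PAX6, the master regulator of eye development, 0.81 (0.76 to 0.85). Several of these factors are also expressed in the retina and cornea. For PAX6 the ratio came from the most abundant of 7 features, at 1.16, while the other 6 together were at 0.00 (−0.09 to 0.10). None of the MAF features with at least 20 counts had a protein match. The 17 genes of the lens capsule and basement membranes had a median of 0.02 at percentile 50.5, with the collagen COL4A1 at 0.58 and the laminin LAMA5 at −0.63. The 15 calpains, calcium pumps and ion transport genes had a median of −0.16 at percentile 12.2, with the water channel AQP1 at −0.81 and the calpain subunit CAPNS1 at 0.76. With only the features that have a protein match, the sign of this median turned, to 0.07 at percentile 61.3. The CAPNS1 ratio came from its most abundant feature, at 0.95, while the other 5 together were at −0.81 (−0.98 to −0.65).

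**Figure D2:**
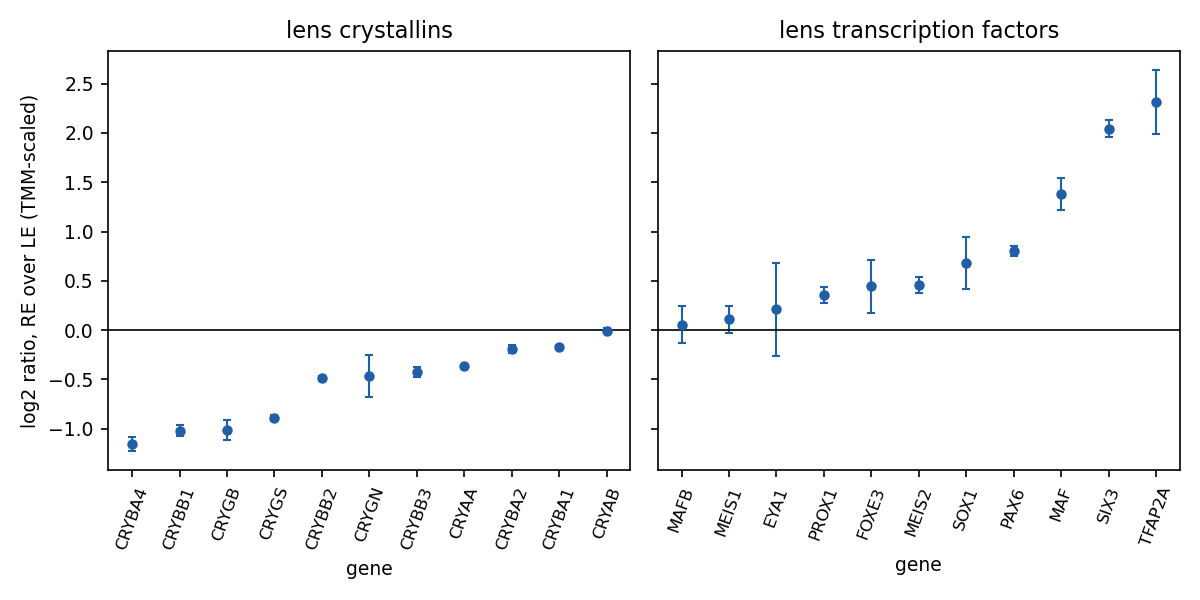
The y axis gives the log2 ratio of RE over LE after scaling by the trimmed mean of M-values, for each lens crystallin and each lens transcription factor with at least 100 counts. Points are single ratios from 1 library each and bars are exact 95% counting intervals. Crystallins lie between −1.15 and −0.01 and transcription factors between 0.05 and 2.31; with total counts all values would be 0.51 lower.

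No retinal list lay outside the central 95% of its random lists. Of 27 genes of rod phototransduction and outer segments, 21 had ratios below 0, with a median of −0.19 at percentile 3.90. GUCA1A, a calcium sensor of the visual cascade, was at −0.61 and the rod transducin subunit GNGT1 at −0.56. The 10 cone genes had a median of 0.17 at percentile 81.1, with PDE6H at −0.47 and the exchanger SLC24A2 at 1.27, or 0.68 with only the features that have a protein match. The 14 bipolar cell genes had a median of −0.07 at percentile 29.5. Among 14 amacrine and horizontal cell genes, 11 had ratios above 0, with a median of 0.26 at percentile 95.4 and TFAP2B at 0.86. Among 12 ganglion cell genes, 11 were above 0, with a median of 0.30 at percentile 97.0. POU4F1, a ganglion cell transcription factor, was at 1.06 and EBF3 at 2.15, but with only the features that have a protein match EBF3 was at 0.48. The 13 genes of Müller glia and astrocytes had a median of 0.15 at percentile 81.7, with the glial water channel AQP4 at 1.06 and APOE at −0.30. The 12 genes of the pigment epithelium and visual cycle had a median of −0.13 at percentile 17.6, with RPE65, the retinoid isomerase, at 0.84 and RDH5 at −0.70. The 8 melanin synthesis genes had a median of 0.30 at percentile 94.7, with OCA2 at 0.52 and PMEL at −0.48.

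Genes of the other parts of the eyeball sample were compared in the same way. Of 28 skeletal muscle genes, which the eye muscles attached to an eyeball express, 23 had ratios below 0, with a median of −0.35 at percentile 0.03. TNNI1 was at −0.88 and the muscle creatine kinase CKM at −0.77, whereas the calcium pump ATP2A1, the most abundant, was at 0.37, which became −0.14 with total counts. The 19 genes of corneal and conjunctival epithelium had a median of −0.16 at percentile 11.01, with KLF5 at 1.54 and KRT4 at −0.94. The less abundant KLF5 features together were at 0.81 (0.45 to 1.18). The 18 genes of corneal and scleral stroma had a median of 0.15 at percentile 86.4, with the corneal proteoglycan KERA at 1.10 and COL8A2 at −0.93. For the 15 genes of iris, ciliary body and trabecular meshwork the median was −0.02 at percentile 45.4, with OPTC at 1.09. For 12 genes of the lacrimal, Harderian and meibomian glands it was 0.20 at percentile 90.8, with LCN2 at 0.85 and AQP5 at −0.59. The 16 genes of vascular endothelium and pericytes had a median of −0.05 at percentile 36.0, with EMCN at 0.63 and KDR at −0.26. Only 2 erythroid genes had enough counts, too few for a median, and of these the haemoglobin chain HBA had 230 and 274 counts and a ratio of 1.06.

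Immune genes did not move together. Of 12 inflammatory cytokine, chemokine and response genes, 10 had ratios above 0 and 5 were at least 2-fold higher in RE, and the median of 0.88 was above 100% of the random lists. For the 6 members with at least 1000 counts the median was 0.25. The monocyte chemokine CCL2 had the largest ratio, 3.50 (3.10 to 3.93), from 57 counts in LE and 371 in RE. SOCS3, a feedback inhibitor of cytokine signals, was at 1.25 and the adhesion molecule VCAM1 at 1.18, while STAT3 was at −0.42. By contrast, 14 of 17 interferon response genes had ratios below 0 and none had an interval above 0, with a median of −0.35 at percentile 1.87. USP18 was at −1.83 and IFIT3 at −1.35, each with about 11% of its counts on features matching primates, and BST2 was at −1.04. With members of at least 1000 counts the median of the interferon response list was −0.15. Without features matching primates it was −0.319 over 16 genes, just inside the −0.323 that bounds the central 95% of the main random lists. With only features that have a protein match it was −0.44 at percentile 0.31. Antigen presentation genes had a median of −0.56 over 9 genes, at percentile 0.17, but the list was split, with 6 ratios below 0 and 3 above, and the 95% interval of its median (−0.68 to 0.14) holds 0. The peptide transporter TAP2 was at −0.78 and the immunoproteasome subunit PSMB8 at −0.65, whereas the most abundant member, B2M, was at 0.21 (0.12 to 0.29). Macrophage and microglia genes had a median of −0.02 over 18 genes, at percentile 56.8, with P2RY12 at 1.12 and C1QA at −0.64. Only 3 genes of neutrophils, lymphocytes and plasma cells could be measured, with a median of −0.04 at percentile 49.9. The 15 complement and acute phase genes had a median of 0.21 at percentile 90.4, with LBP at 0.94 and C4A at −0.67.

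**Figure D3:**
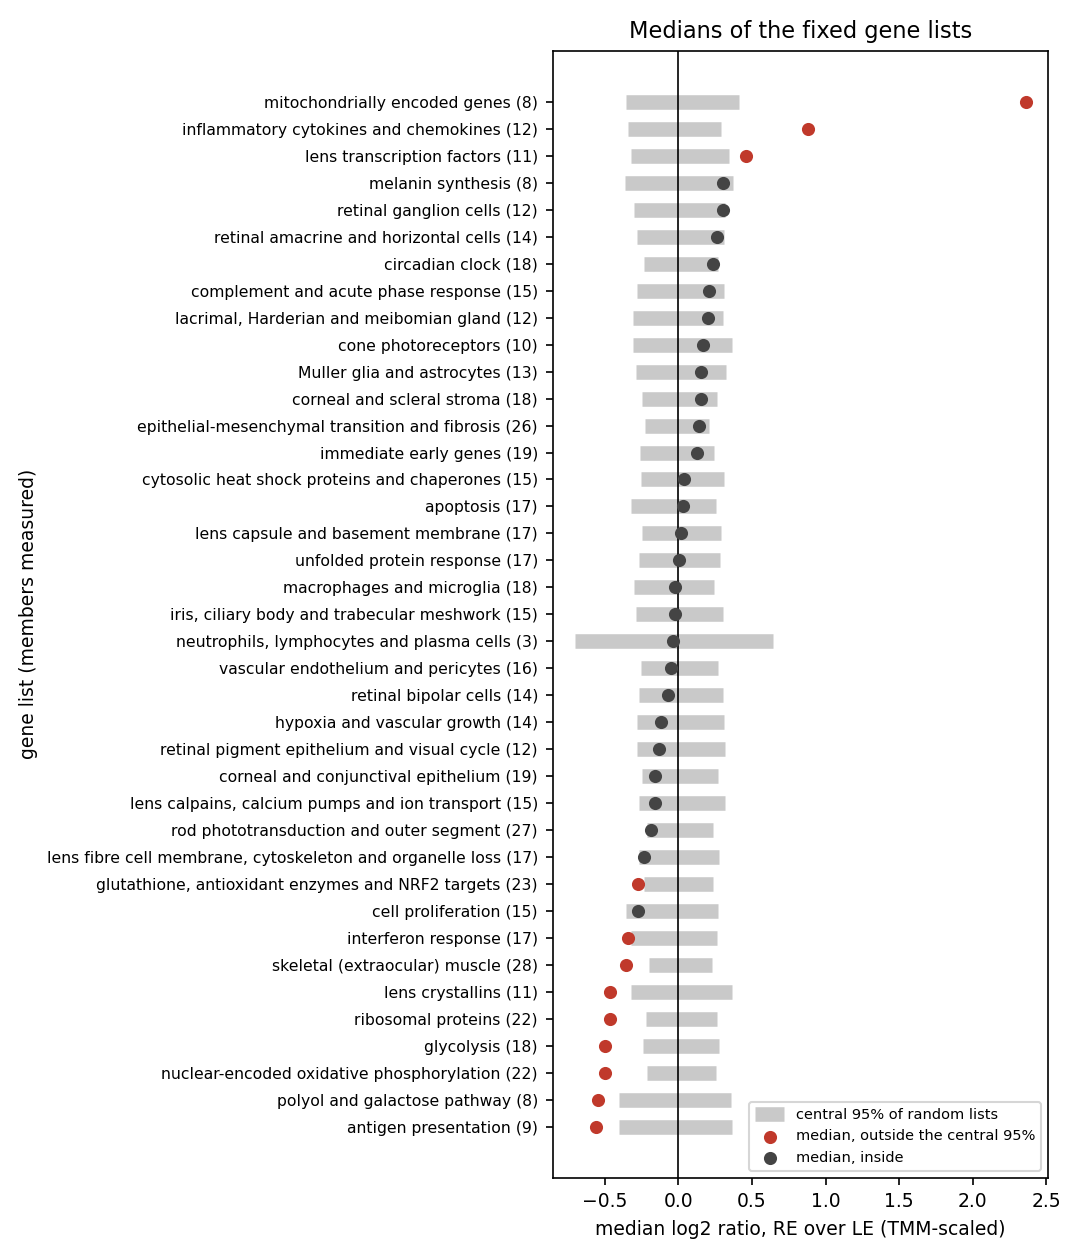
Each point is the median log2 ratio of RE over LE of 1 gene list after scaling by the trimmed mean of M-values, with the number of members measured in parentheses, and each grey bar is the central 95% of 10000 random lists matched on abundance. Medians outside the bar are red. Mitochondrially encoded genes lie highest at 2.36 and antigen presentation lowest at −0.56; with total counts every median would be 0.51 lower.

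Genes of the ribosome, glycolysis and nuclear-encoded oxidative phosphorylation were lower in RE, as were the skeletal muscle genes, whose median was −0.35. Of 22 ribosomal protein genes, 21 had ratios below 0, and the median of −0.47 was below 100% of the random lists. RPS14 was at −1.07. RPSA was at −1.69, but 49.5% of its counts lay on features matching primates, and without these it was at −0.64. Nuclear-encoded oxidative phosphorylation genes had ratios below 0 for 21 of 22 members, with COX4I1 at −0.96 and the ATP synthase subunit ATP5F1B at −0.37, and glycolysis genes for 17 of 18, with the muscle enolase ENO3 at −1.10, ENO1 at −0.92 and ALDOA at −0.55. Both medians were −0.50 and at percentile 0.00, below all random lists. In the polyol and galactose pathway, which converts sugars in the lens and other tissues, all 8 genes had ratios below 0, with a median of −0.55 at percentile 0.21, or −0.31 for the 3 members with at least 1000 counts. KHK was at −0.90 and AKR1A1 at −0.31, while AKR1B10, at −4.79, drew 100% of its counts from features matching primates.

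Among 23 genes of glutathione metabolism, antioxidant enzymes and NRF2 targets, 18 had ratios below 0, with a median of −0.28 at percentile 0.95. The lipid peroxidase GPX4 was at −0.85 and PRDX4 at −1.32, whereas the extracellular superoxide dismutase SOD3 was at 1.63. Heat shock and chaperone genes had a median of 0.04 over 15 genes, at percentile 52.8, with HSP90AA1 at 0.84 and HSPB8 at −0.69. Unfolded protein response genes had a median of 0.00 over 17 genes, at percentile 51.5, with DNAJB9 at 1.28. The 26 genes of epithelial-mesenchymal transition and fibrosis had a median of 0.14 at percentile 91.4, with ZEB2 at 1.17 and TGFBI, with 14.3% of its counts on features matching primates, at −1.03, or −0.75 without these. Apoptosis genes had a median of 0.03 over 17 genes, at percentile 67.8, with XIAP at 0.87 and BAX at −0.71. Proliferation genes had a median of −0.28 over 15 genes, at percentile 7.19, with CCNA2 at 1.00. TOP2A, with 50.3% of its counts on features matching primates, was at −1.14 and without these at −0.08. With the most abundant feature of each symbol the proliferation median was 0.076. Immediate early genes had a median of 0.12 over 19 genes, at percentile 83.8, with EGR1 at 1.57 and FOSB at −0.33, although the less abundant FOSB features together were at 0.63 (0.19 to 1.06). The 18 circadian clock genes had a median of 0.23 at percentile 95.2, with NR1D1 at 0.87 and TEF at −0.63, and the 14 genes of hypoxia and vascular growth had a median of −0.12 at percentile 22.4, with LOX at 1.06.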

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

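The tests in this part were chosen after the results had been seen. Both tables hold signal outside the vole genes that the comparison used, with no control library to set it against, and each count below is above the 3 counts that a true 0 allows. Features whose best match was the human mitochondrial genome held 12607 counts in LE and 655 in RE. Features whose best match was the house mouse mitochondrial genome held 1985 counts in LE and 142 in RE. ALB, whose best match was also a house mouse sequence, had 1056 counts in LE and 24 in RE. Features whose best protein match was a nematode held 24585 counts in LE and 17017 in RE, of which 22687 and 14450 lay on features whose nucleotide match was a rodent sequence. Those with no nucleotide match held 821 counts in LE and 1783 in RE, and the log2 ratios of the 6 with at least 100 counts ranged from −3.57 to 6.28, with a median of 4.02. The most abundant feature with no annotation at all held 1121 counts in LE and 37211 in RE, a log2 ratio of 5.86 (5.77 to 5.94) and 0.186% of the counts in RE.

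The pattern weighed here is that many features with a human best match had few counts in RE. Among 421 such features outside the mitochondrial genome with at least 20 counts, 72.0% were more than 4-fold lower in RE. This held for 0.176% of the 19943 features whose best match was a vole. For most of the 421 features, this argues against vole transcripts that happen to lie nearest to a human entry. These are shares of features and not of counts. All human-matched features outside the mitochondrial genome held 120929 counts in LE and 48172 in RE, less than 4-fold apart. The source of most of these counts is therefore not decided. RNA or reads of human origin in the sample, the library or the sequencing run stay open as an untested source, and no biological explanation was tested. All features with a primate best match took 0.717% of the counts in LE and 0.339% in RE, so the signal is a small part of either library, but it sets the ratio of AKR1B10 and part of those of RPSA, TOP2A and TGFBI.

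Mitochondrially encoded genes took a larger share of RE. Their log2 ratios spanned 2.42, but features of MT-ND2 alone spanned 2.10, so the spread does not decide whether the whole mitochondrial genome rose by 1 factor. Reads spread evenly along the mitochondrial genome, from unprocessed RNA or from DNA, could raise the less abundant genes more. Spearman's rho between abundance and ratio across the 8 genes, which are not independent replicates, was −0.71, which is in that direction, but with so few genes it does not decide the question. A difference in the tissue or in the state of the lens between the eyeballs stays open and untested, because LE and RE are not tied to either state.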

How the results depend on the processing

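The settings without features matching primates, with the symbol from the protein match first and with only features that have a protein match were chosen after the data had been seen, and the others before. Of 105 named genes, 104 kept the sign of their log2 ratio under every setting other than total counts that gave them a value, the exception being CRYAB, whose interval holds 0. AKR1B10 had no value without features matching primates and MAF none with only features that have a protein match. Ratios did leave their main 95% intervals, for 21 genes with the most abundant feature, 30 with totals without crystallin, haemoglobin and mitochondrial genes, 12 with only protein-match features, 5 without primate matches, 2 with DESeq2's factors and 1 with the protein match first. With total counts 98 moved so and 2 more changed sign. Of the 12 lists that stand apart, all kept the sign of their median under the settings other than total counts. Many of these genes were picked for ratios far from 0, and the 12 lists for standing apart, so kept signs are a weak check. In those settings the log2 factor of RE lay between 0.7419 and 0.8246, against 0.8024 in the main one. With DESeq2's size factors 345 symbols were at least 2-fold higher in RE and 119 lower, and all 39 list medians stayed within the 95% interval of the main median, as they did with totals without crystallin, haemoglobin and mitochondrial genes, with members of at least 20 counts, and under the 3 settings chosen later. With no minimum beyond 1 count, 649 symbols were at least 2-fold higher in RE and 492 lower. A minimum of 1000 counts gave 173 and 34 and an interval wholly beyond 2-fold 170 and 29, counts that differ from the main ones at least in part because other numbers of genes were compared or the threshold was stricter. Each feature on its own gave 857 and 939 features, with scaling factors of its own that placed every ratio 0.23 lower, so 2 choices changed together. With total counts 64 symbols were higher and 1674 lower, since that scaling lowers every ratio by the same amount, with ATP2A1 at −0.14 and B2M at −0.30. The same shift turned the lens transcription factors to −0.051 and moved the other medians as follows. In the lens and retina they were −0.74 for lens fibres, −0.49 for the capsule, −0.67 for lens ion transport, −0.70 for rods, −0.58 for bipolar cells, −0.24 for amacrine and horizontal cells, −0.21 for ganglion cells, −0.35 for Müller glia and −0.64 for the pigment epithelium. In other ocular tissue they were −0.67 for corneal epithelium, −0.36 for stroma, −0.53 for the iris, −0.86 for muscle, −0.31 for glands and −0.56 for vessels. Among immune lists they were −0.53 for macrophages, −0.55 for other leukocytes, −0.30 for complement and −1.07 for antigen presentation. For stress and metabolism they were −0.78 for antioxidant enzymes, −0.47 for heat shock proteins, −0.50 for the unfolded protein response, −0.37 for fibrosis, −0.48 for apoptosis, −0.79 for proliferation, −1.01 for glycolysis, −1.01 for oxidative phosphorylation, −0.98 for ribosomal proteins, −0.39 for immediate early genes, −0.28 for the clock and −0.63 for hypoxia. The other 7 medians were lowered by the same amount but stayed within their intervals, which reflect the spread among genes. Among them, the medians of cones, at −0.34, and melanin synthesis, at −0.20, changed sign. Members of at least 1000 counts gave −0.15 for the interferon response, 0.067 for proliferation, 0.25 for inflammatory cytokines and −0.31 for the polyol pathway, with fewer members measured, and the most abundant feature of each symbol gave 0.076 for proliferation; the cause was not tested. Too few counts were found for CRYGA, CRYGD and most members of the blood cell lists, for reasons that were not tested. No paired analysis was possible because there is 1 library per eyeball and the columns carry no replicate number.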

Other observations

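The groups of genes or features in the first 3 paragraphs of this part, and all the tests in its last, were chosen after the data had been seen. Several metabolic pathways that the tables themselves annotate lay below other genes of like abundance in RE. Among 203 annotated pathways with at least 15 measured genes, the lowest relative to random lists of the same abundance was galactose metabolism, with a median log2 ratio of −0.55 and 21 of 23 genes below 0. Fructose and mannose metabolism had a median of −0.43 over 26 genes, the pentose phosphate pathway −0.41 over 24, degradation of the branched-chain amino acids valine, leucine and isoleucine −0.35 over 41, and fatty acid degradation −0.34 over 33. Each of these 5 was at or below percentile 0.04 of its random lists. A gene can belong to several pathways and to the glycolysis or polyol list, so these are not separate results. Features matching primates were kept in them. Mitochondrial ribosomal proteins, which are encoded in the nucleus, had a median of −0.31 with 46 of 61 genes below 0, and proteasome subunits had −0.23 with 23 of 32 below 0, although the annotated proteasome pathway, at −0.07 over 37 genes, did not stand apart. Translation initiation factors, at 0.04 over 44 genes, did not stand apart either. With total counts all of these values would be 0.51 lower.

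The 5 pathways farthest above the median of their random lists were taste transduction, with a median of 0.35 over 33 genes, dorso-ventral axis formation with 0.32 over 19, cell adhesion molecules with 0.26 over 82, signalling by NOD-like receptors with 0.22 over 35 and signalling by tumour necrosis factor with 0.21 over 77. The lowest percentile among these 5 was 98.8. Homeobox transcription factor families had a median of 0.27 over 45 genes at percentile 99.9, and zinc finger genes 0.11 over 198 genes at percentile 99.9. Collagens, at 0.00 over 40 genes, and tubulins, at −0.01 over 14, did not stand apart. Nor did the annotated pathway of antigen processing and presentation, with a median of 0.08 over 29 genes at percentile 75.9, although the shorter list fixed beforehand had lain low. All of the positive medians here are smaller than 0.51 and would lie below 0 with total counts, so they hold only relative to other genes.

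Several groups of features without a name or without a protein match lay above named features of like abundance. Features with at least 100 counts whose best match was a stretch of genome sequence, with no symbol, had a median log2 ratio of 0.20 over 2666 features, against 0.04 for named features matched on abundance, and 0.09 for the highest of 1000 matched sets. Features with no annotation had a median of 0.42 over 418 features, with 0.16 for the highest matched set, and those matching LINE-1 elements or endogenous retroviruses 0.71 over 24, with 0.50. The shift was not particular to features without a name, because named features without a protein match had a median of 0.23 over 1841, against 0.04 for the highest set matched from named features with one. Of features with at least 100 counts in 1 library and at most 3 in the other, 32 were in LE and 3 in RE. Of the 32, 24 had a primate best match and 4 a house mouse one.

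Ribosomal protein, oxidative phosphorylation and glycolysis genes lay below the other genes in RE while lens transcription factors lay above. Skeletal muscle genes lay below as well, with 23 of 28 below 0 and a median of −0.35 (95% interval −0.55 to −0.15). That interval holds the −0.47 of ribosomal proteins, while ATP2A1, the most abundant muscle gene, was at 0.37. These values do not decide how much of the pattern less eye muscle in the sample could account for. The percentiles of these lists come from random lists matched on abundance, so they already allow for a trend with abundance. With only features that have a protein match, the lens transcription factor median was 0.90 above the ribosomal protein median, which argues against reads from unspliced or non-coding RNA in the other features as the whole cause. Such reads within features that have a protein match were not tested. A bias with transcript length, which the tables do not give, and a biological difference between the eyeballs might each account for some or all of the pattern, and both stay open and untested.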
